A study of Mus musculus and Homo sapiens with 18 samples.

How the data were processed

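RNA sequencing was done on sorted mouse T cells and on cultured human aortic endothelial cells (HAoEC). The mouse libraries came from IL-9 fluorescence reporter mice that received 5% imiquimod cream on the skin for 6 weeks, in 3 cycles of 5 days with 13 recovery days, per the labels. CD4+ CD44+ T cells of the spleen were sorted into reporter-positive cells (IL-9+, 5 libraries) and reporter-negative cells (IL-9−, 5 libraries), gated on live CD45.2+ TCR-beta+ CD8− events after red cell lysis. HAoEC were treated with 100 ng/mL IL-9 (4 libraries) or vehicle (4 libraries) for 14 h, per the sample labels. The series text instead gives 16 h of IL-9 and circulating T cells, and the sample labels were followed.

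The authors deposited FPKM (fragments scaled by transcript length and library total) for both organisms. Base calls were converted with bcl2fastq 2.20.0.422 and reads went through Trim Galore, STAR and RSEM, per the submitters' processing notes, which give no versions for these and do not say which step made the FPKM values. The builds were mm10 for mouse and GRCh38 for human, per the same notes. The mouse table held 12873 named genes and 17 blank lines, and no source states the filter that made it shorter than the GENCODE M21 annotation of 55450 genes. All 12873 gene identifiers, version included, were found in GENCODE M21, which gave the coordinates and restored 17 symbols that a spreadsheet had turned into dates. The human table held 58870 lines, of which 45 pseudoautosomal copies were left out, as were 104 genes covering the Y chromosome, XIST, TSIX and HLA-DRB genes that vary in number between people. Of the 58721 lines used, 26011 were 0 in every library. No human annotation was used here, so human genes carry the files' identifiers without coordinates.

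The depth is unknown because the tables hold no counts, so no counting interval is given. FPKM sums per library ranged from 856481 to 943798 in IL-9+ cells, from 804268 to 876237 in IL-9− cells, from 642234 to 710614 in IL-9-treated HAoEC and from 621054 to 654233 in vehicle HAoEC. No pair of libraries held the same values: at most 2.26% of mouse and 0.91% of human genes with an FPKM of 5 or more were equal in any pair.

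Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the moderated test and Benjamini-Hochberg adjustment over all genes tested. Every log2 fold change is on this scale, which understates the change of genes with low values. A gene was tested if its FPKM was at least 1 in as many libraries as the smaller group holds (5 for T cells, 4 for HAoEC), and it passed at an adjusted p under 0.05. IL-9+ was compared with IL-9−, and IL-9-treated with vehicle-treated HAoEC. All adjusted p-values of single genes in the text are from limma. The p-values measure the spread between libraries, since the labels do not state that the libraries of a group came from different animals or independent cultures.

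Gene lists for T cell subsets, cell processes, endothelial functions and marker genes of other cell types were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, for lists with 5 or more tested genes. Named genes followed a rule: the sort genes and Il9 in T cells and the IL-9 receptor and JAK-STAT components in HAoEC; up to 12 genes per direction with the largest log2 fold change among those that passed and moved one way in every pair of libraries; and up to 4 members with the smallest p from each list described. Predicted genes, variable segments of antigen receptors and pseudogenes were not named under the second part. Some genes that the rule would name are not reported here. The tests, lists, naming rule and the alternatives planned were set before the data were examined.

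Libraries of the groups compared share title codes. The deviations of same-code libraries from their group means correlated at 0.433, 0.358, 0.592, 0.288 and 0.426 in T cells and at 0.159, 0.135, 0.311 and 0.176 in HAoEC. A correlation with a library of another code was higher for T cell pair 4 (0.424) and for HAoEC pairs 1, 2 and 4 (0.265, 0.265 and 0.192). Every same-code correlation was over 0.1, so the codes were taken to pair the libraries. A fit with the pair as a block was run beside the unblocked one. The pairing is an assumption, since these correlations do not establish it, least of all in HAoEC. The titles also give a date for some T cell libraries (pairs 1 and 2 one date, pair 3 another, pairs 4 and 5 none). It is called the sort date here, although the titles do not state what was done on it. For HAoEC they give a code P6 or P7 and a code D4 or D9, whose meanings are not stated. Each D code occurs with both P codes in each group, so libraries of a group share D codes and may not be separate cultures. Comparisons were repeated within the sort groups and within P6 and P7. The difference of the IL-9 effect between P6 and P7 was tested as an interaction term, with the D code as an additive term.

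The procedure was tested on simulated data with the real genes' means and spreads. In the T cell layout it called 33 of 100 genes changed 2-fold, 88 of 100 changed 4-fold and 5 of 11796 unchanged ones. In the HAoEC layout these were 93 of 100, 100 of 100 and 13 of 12615. A shifted list was found in both layouts, with 0 of 28 and 0 of 22 other lists called. The changed genes were drawn from those with higher mean values. The simulated genes varied independently, while the estimated inter-gene correlation of the real erythroid markers was 0.953. The simulation therefore does not test false calls of lists whose genes are correlated.

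Alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean FPKM of at least 5, rescaling to a common total (TPM), median-of-ratios scaling, quantile normalisation, array weights, robust moderation, an absolute log2 fold change of at least 1, the pair block, the sort batch or title codes as covariates, and leaving out each library. For HAoEC, a smooth trend (loess span of 0.5) on GC content and transcript length was also removed from each library, with values taken from mouse genes of the same symbol.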

Results

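Gene expression was measured by RNA sequencing in 18 libraries from 2 experiments. The first compared CD4+ CD44+ T cells from the spleens of imiquimod-treated IL-9 reporter mice, sorted by reporter fluorescence into IL-9+ (n = 5) and IL-9− (n = 5) libraries. Imiquimod cream activates innate immune sensing in the skin and is used to model psoriasis. The second compared human aortic endothelial cells (HAoEC), primary cells that line the aorta, after IL-9 (n = 4) or vehicle (n = 4). Values are FPKM as mean ± SD over the libraries of a group, and fold changes are on the log2(FPKM + 1) scale with their standard error (SE). Mouse positions are on mm10 as given by GENCODE M21.

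In the first comparison, which asked how T cells that express IL-9 differ from those that do not, Il9 itself measured 22.5 ± 11.8 FPKM in IL-9+ and 5.87 ± 4.39 in IL-9− cells (n = 5 each). IL-9+ libraries held more transcripts of Slpi, a secreted protease inhibitor, with 215 ± 92.3 against 13.9 ± 12.6 FPKM, and of Il1b, an inflammatory cytokine, with 416 ± 169 against 45.4 ± 62.9. They held less of Foxp3, the defining transcription factor of regulatory T cells, with 11.9 ± 3.15 against 45.3 ± 20.2 FPKM, and of Tigit, an inhibitory receptor, with 73.3 ± 30.3 against 272 ± 75.4. Of marker genes of other cell types, 13 of 16 for monocytes and macrophages, 2 of 13 for neutrophils, 7 of 19 for B cells and 2 of 5 for basophils, mast cells and eosinophils were higher in the IL-9+ libraries, and the T cell receptor component Cd3e was lower, with 91.9 ± 15.6 against 200 ± 48.1 FPKM. Of 31 cell cycle genes 10 were higher and of 30 interferon-stimulated genes 5, and each list had an adjusted p of 0.4 with an estimated correlation.

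Of 12167 genes tested, 755 passed, with 533 higher and 222 lower in IL-9+ cells. Among these, 748 moved one way in all 5 pairs and 562 differed at least 2-fold (486 higher, 76 lower). The fit with the pair as a block called 2493 genes, 1397 higher and 1096 lower, and held all 755. Within the first sort date (2 pairs) 1322 genes passed, 949 higher and 373 lower, and within the undated sorts (2 pairs) 2877 passed, 1289 higher and 1588 lower. The second sort date holds 1 pair and allows no test. Of the 755 genes, 100% had the same sign within the first date and the undated sorts, and 99.7% within the second date. They were called from these libraries together, so these shares and the 748 are not an independent replication. The division into higher and lower depended on the scaling: it was 510 to 454 after rescaling to TPM, 593 to 124 with median-of-ratios scaling and 460 to 376 after quantile normalisation. The median log2 fold change of all genes was −0.09 as deposited, −0.18 with TPM, 0.01 with median-of-ratios scaling and −0.16 with quantile normalisation. The count was 1624 without IL-9+ replicate 3, between 230 and 486 without IL-9− replicate 1, 2, 3 or 4 or without IL-9+ replicate 2, 4 or 5, and 350 without the undated sorts.

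Il9 (ENSMUSG00000021538.3, chromosome 13, 56479277 to 56482246, minus strand) was higher in 5 of 5 IL-9+ libraries than in their paired IL-9− libraries, with a log2 difference of 2.04 (SE 0.60). Its adjusted p was 0.0669 in the unblocked fit and 0.0123 with the pair block. The log2 difference of Il9 was 2.04 within the first sort date, 3.65 in the pair of the second and 1.23 in the undated sorts. The other genes of the sort gate gave no call. Cd4 measured 94.2 ± 56.2 against 152 ± 39.8 FPKM (log2 difference −0.92, adjusted p = 0.218), and Ptprc, which encodes CD45, measured 486 ± 109 against 635 ± 152. Cd44, a marker of antigen-experienced T cells, measured 162 ± 34.8 against 149 ± 82. The T cell receptor constant genes Trbc1 and Trbc2 measured 381 ± 263 and 658 ± 447 FPKM in IL-9+ cells and 419 ± 132 and 687 ± 244 in IL-9− cells. Without the undated sorts the log2 differences of Cd44, Trbc1 and Trbc2 changed sign to −0.27, 0.16 and 0.30, none past the threshold. Cd8a is not analysed here.

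The 12 genes with the largest increase in IL-9+ cells were Clec4e, F10, Iglc2, Cd14, Fcer1g, Acod1, Slpi, Cd36, Wfdc17, Hcar2, Tyrobp and Il1b, with log2 fold changes between 3.96 and 4.43. Wfdc17 (ENSMUSG00000069792.5, chromosome 11, 83703991 to 83706268, plus strand), a small secreted protein gene of myeloid cells, rose from 3.17 ± 2.53 to 61.7 ± 10.5 FPKM (log2 fold change 4.08, SE 0.34, adjusted p = 0.000366). Slpi (ENSMUSG00000017002.14, chromosome 2, 164354070 to 164389095, minus strand) had a log2 fold change of 4.12 (SE 0.48, adjusted p = 0.00214). Iglc2 (ENSMUSG00000076937.3, chromosome 16, 19198396 to 19200351, minus strand), an immunoglobulin light chain constant gene whose near-identical neighbours can share reads with it, measured 216 ± 90 against 13.3 ± 11.5 FPKM. Clec4e (ENSMUSG00000030142.10, chromosome 6, 123281789 to 123289870, minus strand), a myeloid pattern recognition receptor, measured 199 ± 105 against 17.9 ± 28.4. Cd14, a lipopolysaccharide co-receptor of monocytes, had a log2 fold change of 4.16 (adjusted p = 0.0472, and 0.0542 with a pseudocount of 0.1). Il1b (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139, minus strand) had a log2 fold change of 3.96 (SE 0.71, adjusted p = 0.0123). All 12 genes were higher in 5 of 5 pairs, which the naming rule required. Without IL-9+ replicate 5, Clec4e, Cd14, Fcer1g and Tyrobp did not pass. Acod1 had an adjusted p of 0.0553 without the undated sorts, with a log2 difference of 4.56.

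The 12 genes with the largest decrease were Tnfrsf9, Tigit, Itgb8, Foxp3, Rab6b, Sh3rf1, Lrig1, Coq8a, Ikzf4, Plcxd1, Bmyc and Gimap7. Their log2 fold changes lay between −2.18 and −1.41, and each was lower in 5 of 5 pairs, as the naming rule required. Tnfrsf9 (ENSMUSG00000028965.13, chromosome 4, 150914562 to 150946102, plus strand), which encodes the costimulatory receptor 4-1BB, fell from 489 ± 248 to 123 ± 117 FPKM (log2 fold change −2.18, SE 0.48, adjusted p = 0.0249). Tigit (ENSMUSG00000071552.5, chromosome 16, 43648867 to 43664146, minus strand) had a log2 fold change of −1.91 (SE 0.28, adjusted p = 0.00611). Foxp3 (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245, plus strand) had one of −1.74 (SE 0.33, adjusted p = 0.015), with −0.58 within the first sort date, −2.31 in the second and −2.62 in the undated sorts. Itgb8, an integrin subunit that activates TGF-beta, fell from 34.4 ± 10.9 to 9.19 ± 4.44 FPKM. Without the undated sorts, which leaves 3 pairs, Foxp3 (log2 difference −1.15, adjusted p = 0.172), Tigit (−1.41, adjusted p = 0.0714) and Tnfrsf9 (−1.71, adjusted p = 0.264) did not pass, nor did Lrig1 (adjusted p = 0.0661), Coq8a (0.082), Ikzf4 (0.0775), Plcxd1 (0.166), Bmyc (0.269) and Gimap7 (0.317).

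**Figure D1:**
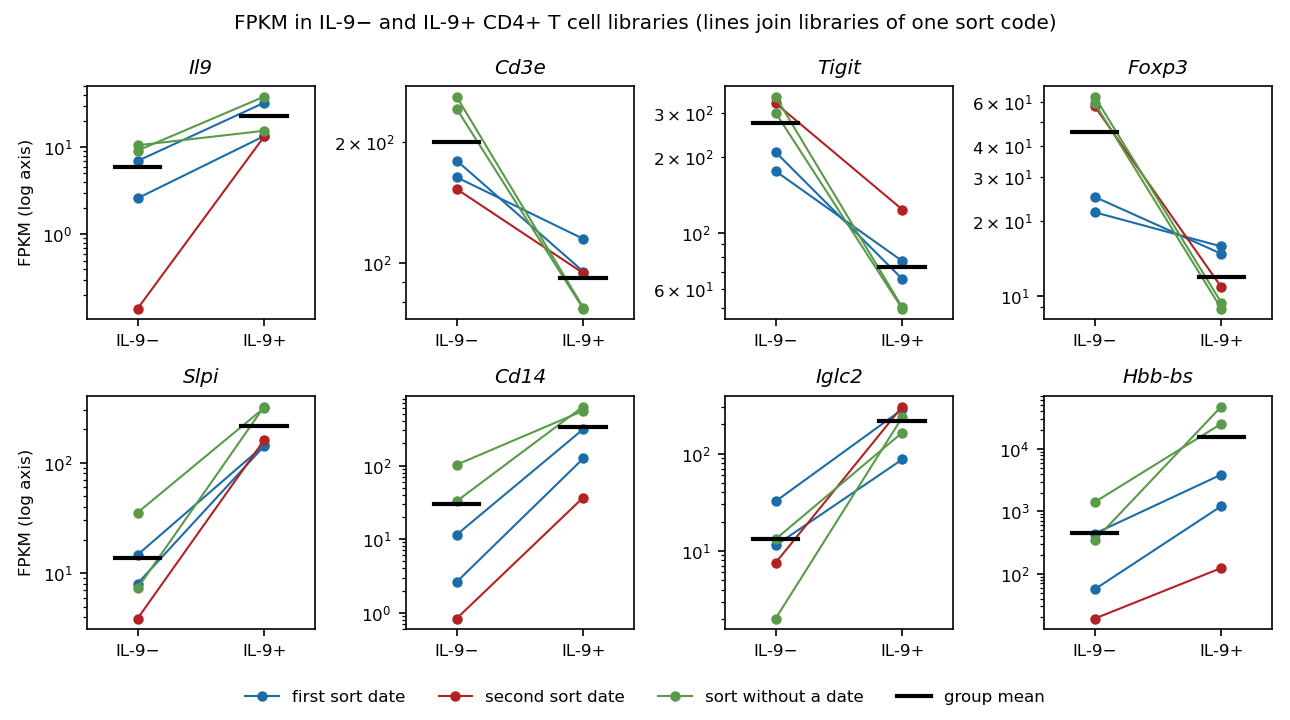
FPKM (log axis) of 8 genes in the IL-9− and IL-9+ library of each of the 5 pairs, joined by lines coloured by sort batch, with black lines at the group means. Il9 and Slpi were higher and Tigit and Foxp3 lower in the IL-9+ library of all 5 pairs, while Hbb-bs spread over a wide range in the IL-9+ libraries.

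Regulatory T cell genes fell as a group: of 19 tested, 7 were lower and 0 higher over all genes, and 8 were lower and 1 higher adjusted over the list alone. Their median log2 difference was −1.14 (camera adjusted p = 5.55e-05, and adjusted p = 0.347 with an estimated correlation). The members lower included Tnfrsf18, which encodes the receptor GITR, with 160 ± 48.5 against 412 ± 101 FPKM. The list median was −0.58 within the first sort date, −0.44 in the second and −1.44 in the undated sorts. Pan T cell markers moved in the same direction. Of 17 tested, 2 were lower over all genes (Cd3e and Zap70) and 4 adjusted over the list alone, with a median of −0.77 (camera adjusted p = 8.48e-05, and adjusted p = 0.537 with an estimated correlation). Their median was −0.38 within the first sort date, 0.06 in the second and −1.50 in the undated sorts. The IL-9+ libraries of the undated sorts also stood apart in composition: ribosomal protein genes held 12.26% and 13.74% of their FPKM, against 25.55% and 24.09% in the paired IL-9− libraries, and mitochondrially encoded genes 19.7% and 18.67%, against 14.61% and 12.92%. Tnfrsf18 (adjusted p = 0.0941), Cd3e (0.0911) and Zap70 (0.122) did not pass without the undated sorts. T follicular helper genes had a median of −0.50, with 1 of 16 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.0466, and adjusted p = 0.735 with an estimated correlation). The member past the threshold was Hif1a, an oxygen-sensing transcription factor, at −0.58, and the list passed neither with TPM (adjusted p = 0.0654) or quantile normalisation (adjusted p = 0.0679) nor without the undated sorts (adjusted p = 0.221). Hif1a did not pass with median-of-ratios scaling (adjusted p = 0.089) or without the undated sorts (adjusted p = 0.164).

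Regulators and receptors of IL-9-producing (Th9) cells did not pass as a group. Of 19 tested, 3 were higher and 3 lower over all genes (4 and 5 adjusted over the list alone), with a median of −0.45, a mean of 0.06 and a camera adjusted p of 0.433. The list median was below 0 in 5 of 5 pairs (mean −0.343, SD 0.167), beside a mean of −0.718 (SD 0.715) for pan T cell markers. Pparg, a nuclear receptor linked to IL-9 production in T cells, rose from 1.59 ± 1.01 to 9.09 ± 4.45 FPKM (log2 fold change 1.92, SE 0.39, adjusted p = 0.0198). Without the undated sorts its log2 difference was 1.95 and its adjusted p 0.0928. Batf3 rose by 2.04 and Spi1, which encodes PU.1, a factor of Th9 and of myeloid cells, by 3.21 on the log2 scale. Monocyte and macrophage markers were higher in the same libraries, with a median log2 difference of 3.14. Of 15 Th2 genes 3 were higher and 0 lower over all genes (5 and 3 adjusted over the list alone; camera adjusted p = 0.369), namely Pparg, the prostaglandin D2 synthase gene Hpgds, at 1.32, and the steroid-producing enzyme gene Cyp11a1, at 1.24. Hpgds did not pass with a pseudocount of 0.1 (adjusted p = 0.0648), TPM (0.0584) or quantile normalisation (0.0639), nor Cyp11a1 with quantile normalisation (adjusted p = 0.0601), and without the undated sorts neither did (adjusted p = 0.155 and 0.0648), nor Batf3 (0.159), Ly6c2 (0.0511) or Cxcr6 (0.133). Of 16 Th1 genes 2 were higher, Ccl3 and Ly6c2 (2 higher and 1 lower adjusted over the list alone). The Th1 list had a median of −0.26 against a mean of 0.27 and an upward test direction (camera adjusted p = 0.67). Of 15 Th17 genes 1 was lower, Cxcr6, at −1.04 (camera adjusted p = 0.972), which had an adjusted p of 0.0695 with median-of-ratios scaling. With the pair block 3 Th17 genes were higher and 2 lower, with Blk (2.24, adjusted p = 0.00211) and Tmem176b (1.38, adjusted p = 0.00871) higher and Rora (−0.84, adjusted p = 0.0316) lower.

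Of 41 secreted cytokine genes 6 were higher over all genes, and 8 were higher and 1 lower adjusted over the list alone. The median of the list was 0.23 (camera adjusted p = 0.0278, and adjusted p = 0.728 with an estimated correlation), and −0.10 within the first sort date. The list did not pass with the pair block (adjusted p = 0.235), with median-of-ratios scaling (adjusted p = 0.0845), by fry (adjusted p = 0.308) or without the undated sorts (adjusted p = 0.677). The chemokine gene Ccl3 rose from 148 ± 60.9 to 1043 ± 394 FPKM (log2 fold change 2.87, SE 0.37, adjusted p = 0.00309). Il6 rose from 4.41 ± 4.98 to 48.9 ± 33.4 and Osm, which encodes oncostatin M, from 8.26 ± 3.44 to 88 ± 71.2. Osm did not pass without the undated sorts (adjusted p = 0.0725). Markers of monocytes and neutrophils, which can also express Ccl3, Il6 and Osm, were higher in the same libraries.

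Of 31 cell cycle genes 10 were higher over all genes and 21 adjusted over the list alone, 0 lower in both, with a median of 1.16 (camera adjusted p = 2.89e-12, adjusted p = 0.4 with an estimated correlation, and fry adjusted p = 0.0578). Mki67, a marker of cycling cells, rose from 23 ± 11.8 to 63.1 ± 10.4 FPKM (log2 fold change 1.56, SE 0.34, adjusted p = 0.0237), and Rrm2, Birc5 and Ube2c rose by between 1.44 and 1.65. The list median was 1.36 within the first sort date, 2.42 in the second and 0.27 in the undated sorts. Of 30 interferon-stimulated genes 5 were higher over all genes and 11 adjusted over the list alone, 0 lower in both, with a median of 0.80 (camera adjusted p = 1.45e-06, adjusted p = 0.4 with an estimated correlation, and fry adjusted p = 0.057). Monocyte and macrophage markers and neutrophil markers had medians of 3.14 and 3.57 in the same libraries. Isg15 rose from 26.6 ± 9.08 to 100 ± 45.7 FPKM and Ifi204 from 4.31 ± 2.42 to 45.6 ± 14.9. Cholesterol synthesis genes had a median of 0.24, with 1 of 19 higher, Sc5d, in both counts (over all genes and adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.4 with an estimated correlation). Sc5d did not pass without the undated sorts (adjusted p = 0.115).

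Marker genes of other cell types were measured beside these groups. Of 16 monocyte and macrophage markers, 13 were higher over all genes and 16 adjusted over the list alone (median 3.14, camera adjusted p = 4.89e-15, and adjusted p = 0.237 with an estimated correlation), and 1 of the 20 listed, Ly6c2, is also a Th1 gene. Their most abundant member, Lyz2, measured 852 FPKM in IL-9+ and 58.1 in IL-9− libraries on average, and Cd68 rose from 8.34 ± 2.37 to 71.3 ± 28.3. Of 13 neutrophil markers, 2 were higher over all genes and 12 adjusted over the list alone (median 3.57, camera adjusted p = 5.47e-07, and adjusted p = 0.4 with an estimated correlation), and S100a9 averaged 12000 against 1310 FPKM. Of 19 B cell markers 7 were higher over all genes and 13 adjusted over the list alone (median 2.34, camera adjusted p = 3.67e-10, and adjusted p = 0.4 with an estimated correlation). They included the class II genes H2-Ab1, H2-Aa, H2-Eb1 and Cd74, which other antigen-presenting cells also express, and Igkc averaged 4280 against 640 FPKM. These 4 class II genes did not pass without the undated sorts (adjusted p = 0.0953, 0.098, 0.127 and 0.147), with log2 differences of 2.94, 3.39, 3.30 and 2.51. Of 5 basophil, mast cell and eosinophil markers 2 were higher over all genes (Mcpt8 and Prss34) and 5 adjusted over the list alone, with a median of 3.15 (camera adjusted p = 0.00028, and adjusted p = 0.237 with an estimated correlation). Prss34 did not pass without the undated sorts (adjusted p = 0.0696).

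Dendritic cell markers had 2 of 6 members higher in both counts, Itgax and Batf3 (median 0.93, camera adjusted p = 0.0046, and adjusted p = 0.237 with an estimated correlation). Plasma cell markers had 1 of 11 higher, Mzb1, and 4 adjusted over the list alone (median 1.17, camera adjusted p = 0.0204, and adjusted p = 0.468 with an estimated correlation). Neither the list (adjusted p = 0.0969) nor Mzb1 (adjusted p = 0.0688) passed without the undated sorts. Of 10 erythroid markers 0 passed over all genes or adjusted over the list alone, and 9 passed with the pair block. Their median was 3.11 (camera adjusted p = 0.000118, and adjusted p = 0.479 with an estimated correlation). The beta-globin gene Hbb-bs measured 15700 ± 20700 against 452 ± 561 FPKM (log2 difference 4.29, adjusted p = 0.125, and 0.00323 with the pair block). Haemoglobin genes held between 0.03% and 12.01% of all FPKM in IL-9+ and between 0.01% and 0.44% in IL-9− libraries. NK cell and CD8 or gamma-delta T cell markers did not pass (camera adjusted p = 0.0972 and 0.0589), and the latter passed with the pair block (adjusted p = 0.0384).

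**Figure D2:**
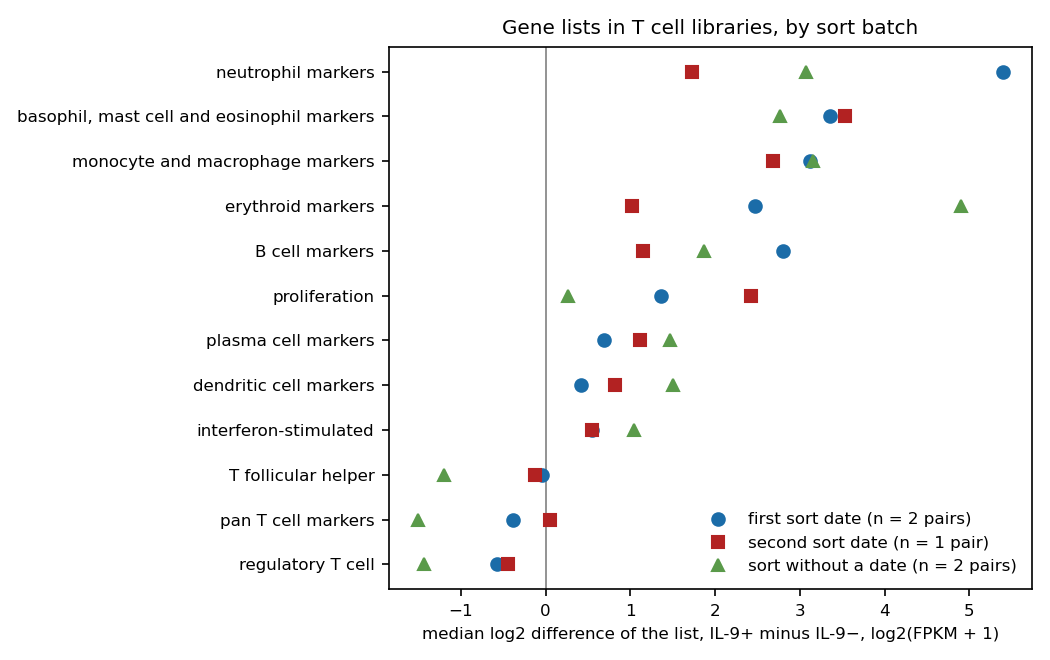
Median log2 difference in log2(FPKM + 1), IL-9+ minus IL-9−, of 12 gene lists within each of the 3 sort batches, 1 point per batch. Monocyte and macrophage markers lay between 2.69 and 3.16 in all 3 batches, and pan T cell markers between −1.50 and 0.06.

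Of 29 lists tested, 14 passed camera at the preset correlation, 11 upward and 3 downward, 0 passed with an estimated correlation, and 4 passed fry (regulatory T cell genes and the monocyte, dendritic cell and basophil markers). With the pair block, stress and immediate early genes passed upward (adjusted p = 0.0205, with 0.128 unblocked) and glycolysis and hypoxia genes downward (adjusted p = 0.0137, with 0.0972 unblocked). With the block the members higher and lower over all genes were 2 and 12 of the regulatory T cell list, 0 and 5 of the pan T cell, 0 and 3 of the T follicular helper, 5 and 7 of the Th9, 5 and 4 of the Th2, 4 and 2 of the Th1, 10 and 10 of the secreted cytokine, 18 and 0 of the cell cycle, 15 and 1 of the interferon-stimulated and 4 and 0 of the cholesterol synthesis list. For markers these were 16 and 0 for monocytes and macrophages, 13 and 0 for neutrophils, 17 and 0 for B cells, 4 and 0 for basophils, mast cells and eosinophils, 3 and 0 for dendritic cells and 6 and 1 for plasma cells.

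In the second comparison, which asked how endothelial cells of the aorta respond to IL-9, the genes SELE, VCAM1 and CXCL8 were lower after 14 h of IL-9, and the Notch ligand gene DLL4, 11 of 26 endothelial identity genes and 10 of 24 junction genes were higher. Each of the 2 lists had an adjusted p of 0.161 with an estimated correlation. SELE, which encodes the leukocyte adhesion molecule E-selectin, measured 1.39 ± 0.847 FPKM with IL-9 and 92.5 ± 75.7 with vehicle (n = 4 each), and VCAM1, another adhesion molecule, 13.9 ± 9.95 against 133 ± 34.6. The neutrophil chemokine gene CXCL8 measured 7.12 ± 1.29 against 43.8 ± 29.8. CLDN5, a tight junction protein of endothelium, measured 368 ± 52.2 against 94.7 ± 7.47, and the chemokine receptor gene CXCR4 32.5 ± 4.04 against 5.43 ± 0.795. IL9R, the gene of the receptor's specific chain, stayed between 0.02 and 0.09 FPKM in all 8 libraries.

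Of 12944 genes tested, 3068 passed, with 1107 higher and 1961 lower with IL-9. Of these, 3041 moved one way in all 4 pairs, and 246 changed at least 2-fold (91 higher, 155 lower). The fit with the pair as a block called 3119 genes, 1180 higher and 1939 lower, and held 2718 of the 3068. Within the cultures titled P6 (2 pairs) 2685 genes passed, 1055 higher and 1630 lower, and within those titled P7 (2 pairs) 1470, 610 higher and 860 lower. Of the 3068 genes, 100% had the same sign in each. They were called from these libraries together, so this share and the 3041 are not an independent replication. The division into higher and lower was 1452 to 1599 with median-of-ratios scaling, 1495 to 1489 with quantile normalisation and 879 to 2486 with TPM. The median log2 fold change of all genes was −0.03 as deposited, −0.10 with TPM, 0.00 with median-of-ratios scaling and 0.01 with quantile normalisation. Called genes differed in composition. The median GC content of their mouse counterparts was 54.6% for higher and 46.6% for lower genes, and the median transcript length 3076 and 4086 bases. Across genes with a mouse counterpart, the log2 fold change correlated with GC content at 0.411 and with length at −0.269 (Spearman). With that trend removed from each library, 1326 genes were higher and 1295 lower, against 959 and 1693 of the same genes before. The count was 1944 without IL-9 replicate 1 and 2028 without vehicle replicate 1.

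Most genes of the receptor and its signalling chain did not pass or were too low to test. IL9R averaged 0.05 ± 0.0316 FPKM with IL-9 and 0.0225 ± 0.005 with vehicle, and IL2RG, which encodes the shared signalling chain of the receptor, ranged from 0.04 to 0.42 FPKM. Both were below the level required for a test, as was JAK3. Of 10 members tested, 2 were lower and 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 0.805). JAK1, a kinase bound to the receptor, fell from 121 ± 10.8 to 73 ± 8.65 FPKM (ENSG00000162434.12, log2 fold change −0.73, SE 0.10, adjusted p = 0.000957). STAT5B fell by 0.42 (adjusted p = 0.00273). STAT3 and STAT6, transcription factors downstream of cytokine receptors, had adjusted p-values of 0.526 and 0.917, JAK2 one of 0.308 and IL4R one of 0.0629. Known targets of STAT signalling were higher as a group, with 5 of 21 higher and 0 lower, over all genes and adjusted over the list alone (median 0.19, camera adjusted p = 0.0182, and adjusted p = 0.465 with an estimated correlation). SOCS3, a feedback inhibitor of cytokine signalling, rose from 2.32 ± 0.456 to 5.47 ± 1.22 FPKM (log2 fold change 0.95, SE 0.15, adjusted p = 0.0023) and SOCS1 from 1.15 ± 0.492 to 2.18 ± 0.191. With the GC and length trend removed the list did not pass (adjusted p = 0.246), nor without IL-9 replicate 2 (adjusted p = 0.065) or vehicle replicate 2 (adjusted p = 0.097).

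The 12 genes with the largest increase were KIT, CXCR4, EFNA1, WNT9A, N4BP3, DLL4, NRARP, CLDN5, GPR146, SCHIP1, APLN and PRR5L. Their log2 fold changes lay between 1.67 and 2.55, and all were higher in 4 of 4 pairs, as the naming rule required. KIT (ENSG00000157404.15), the stem cell factor receptor, rose from 1.06 ± 0.669 to 10.6 ± 1.41 FPKM (log2 fold change 2.55, SE 0.21, adjusted p = 9.41e-05). CXCR4 (ENSG00000121966.6) had a log2 fold change of 2.38 (SE 0.12, adjusted p = 8.01e-06), and CLDN5 (ENSG00000184113.9) one of 1.94 (SE 0.10, adjusted p = 9.83e-06). The Notch ligand gene DLL4 (ENSG00000128917.8) rose from 19.7 ± 13.8 to 69.9 ± 12.5 FPKM (log2 fold change 2.05, SE 0.45, adjusted p = 0.0109), with 2.78 in P6 and 1.32 in P7. NRARP, a Notch target, rose by 2.00, and the ephrin ligand gene EFNA1 by 2.32 on the log2 scale.

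The 12 genes with the largest decrease were SELE, VCAM1, EGR1, KAZALD1, ATOH8, CXCL8, C14orf132, PTGS2, CXCL12, VEGFC, GSE1 and NEAT1. Their log2 fold changes lay between −4.87 and −2.08, and all were lower in 4 of 4 pairs, as the naming rule required. SELE (ENSG00000007908.16) had a log2 fold change of −4.87 (SE 0.61, adjusted p = 0.000749), with −5.74 in P6 and −3.99 in P7, and VCAM1 (ENSG00000162692.12) one of −3.38 (SE 0.42, adjusted p = 0.000716), with −2.89 in P6 and −3.88 in P7. VEGFC (ENSG00000150630.4), a growth factor for lymphatic vessels, fell from 27.2 ± 2.24 to 5.6 ± 1.03 FPKM (log2 fold change −2.10, SE 0.11, adjusted p = 9.83e-06). PTGS2, which encodes cyclooxygenase-2, fell from 11.3 ± 8.03 to 1.37 ± 0.561, and NEAT1, a nuclear noncoding RNA, from 285 ± 32 to 67.2 ± 11.6.

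**Figure D3:**
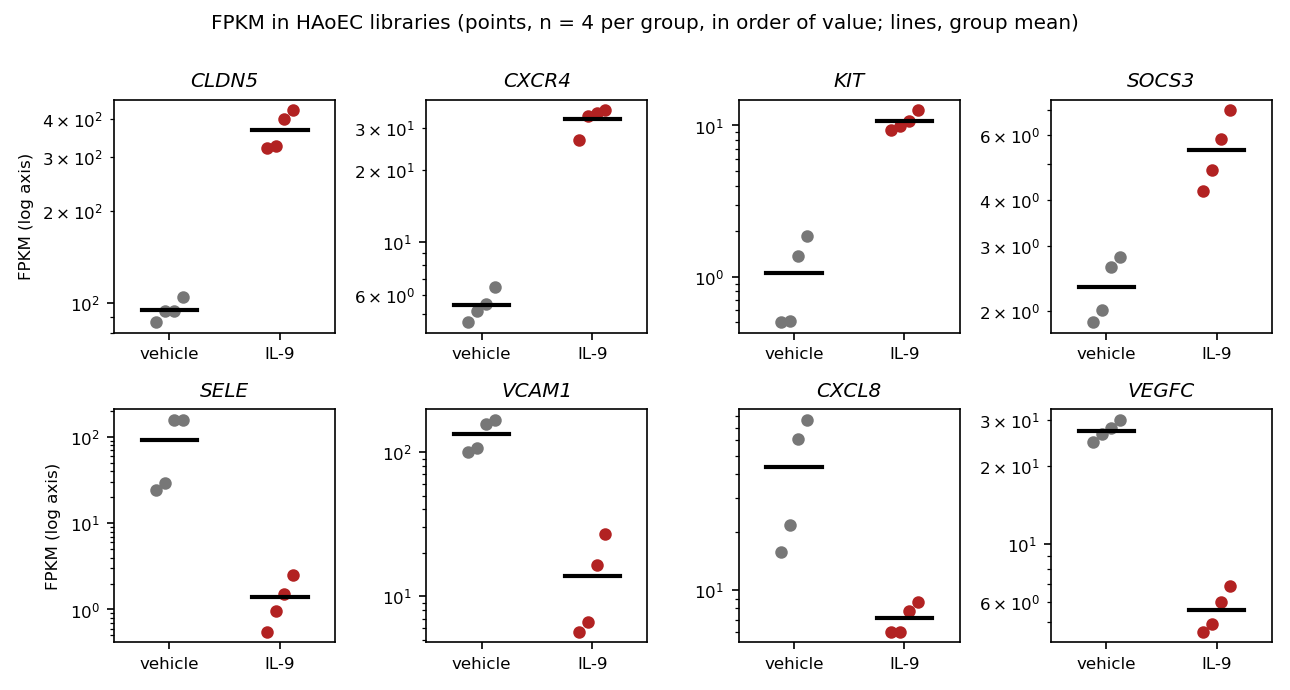
FPKM (log axis) of 8 genes in vehicle and IL-9-treated HAoEC, 4 libraries per group as points, with a line at each group mean. SELE, VCAM1, CXCL8 and VEGFC lay lower and CLDN5, CXCR4, KIT and SOCS3 higher in the IL-9 group.

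Endothelial identity genes rose as a group, with 11 of 26 higher and 2 lower, over all genes and adjusted over the list alone (median 0.16, camera adjusted p = 0.000697, and adjusted p = 0.161 with an estimated correlation). ROBO4, a stabiliser of vessels, rose from 81.7 ± 9.38 to 152 ± 10.4 FPKM (log2 fold change 0.89, SE 0.09, adjusted p = 0.000251), and ERG, a transcription factor of endothelium, by 0.43. Junction and barrier genes rose, with 10 of 24 higher and 2 lower over all genes and 11 and 3 adjusted over the list alone (median 0.20, camera adjusted p = 0.00346, and adjusted p = 0.161 with an estimated correlation). The gap junction gene GJA5, a marker of arterial endothelium, rose from 8.84 ± 1.83 to 24.1 ± 2.92, and GJA1, another connexin, fell from 166 ± 11.5 to 108 ± 7.24. The medians were 0.19 in P6 and 0.19 in P7 for identity, and 0.19 in P6 and 0.18 in P7 for junctions. Junction genes did not pass with quantile normalisation (adjusted p = 0.0572). Of 33 angiogenesis and Notch genes 11 were higher and 4 lower over all genes, and 13 and 7 adjusted over the list alone (camera adjusted p = 0.0607). APLN, an angiogenic peptide gene, rose by 1.68, and ESM1, a marker of sprouting endothelium, fell from 197 ± 44.3 to 52.7 ± 6.66 FPKM.

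NF-kB targets and cytokines had 13 of 29 members lower and 4 higher over all genes, and 14 and 6 adjusted over the list alone. Their median was −0.51 and the camera adjusted p 0.0513, which was 0.00806 with the pair block and 0.605 with an estimated correlation. TRAF1, an adaptor of TNF receptors, fell from 4.42 ± 0.501 to 0.62 ± 0.0816 FPKM (log2 fold change −1.74, SE 0.09, adjusted p = 9.83e-06), NFKB1 fell by 0.62 and the chemokine gene CX3CL1 fell by 1.05 on the log2 scale. Leukocyte adhesion genes went both ways, with 5 of 19 higher and 4 lower over all genes, and 5 and 5 adjusted over the list alone. Their median was 0.10, their mean −0.38 and the test direction upward (camera adjusted p = 0.356). ICAM2 rose from 224 ± 9.58 to 383 ± 51.7 FPKM while SELE, VCAM1 and CX3CL1 fell. Stress and immediate early genes fell, with 8 of 25 lower and 1 higher over all genes and 10 and 1 adjusted over the list alone (median −0.27, camera adjusted p = 0.00116, and adjusted p = 0.233 with an estimated correlation). EGR1 fell from 21.1 ± 10.2 to 2.64 ± 0.0829 FPKM and ZFP36, which encodes an mRNA-destabilising protein, from 13.6 ± 1.88 to 4.54 ± 0.262.

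Interferon-stimulated genes rose as a group, with 12 of 32 higher and 2 lower over all genes and 13 and 3 adjusted over the list alone (median 0.18, camera adjusted p = 0.00346, and adjusted p = 0.465 with an estimated correlation). OAS1, an antiviral enzyme gene, rose from 4.65 ± 0.749 to 8.66 ± 0.497 FPKM, and GBP1, an interferon-induced GTPase gene, fell from 22.5 ± 5.54 to 10.4 ± 2.35. Antigen presentation genes had a median of 0.10, with 2 of 18 higher and 1 lower in both counts (camera adjusted p = 0.025, and adjusted p = 0.465 with an estimated correlation). NLRC5, a transactivator of class I genes, rose by 0.89, and CD274, which encodes PD-L1, fell by 0.48. The list did not pass with quantile normalisation (adjusted p = 0.157), with the GC and length trend removed (adjusted p = 0.695) or without IL-9 replicate 2 (adjusted p = 0.051).

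Cholesterol synthesis genes fell, with 10 of 19 lower and 0 higher over all genes and 12 and 1 adjusted over the list alone (median −0.41, camera adjusted p = 0.00116, and adjusted p = 0.233 with an estimated correlation). HMGCS1, an enzyme gene of the mevalonate pathway, fell from 22.5 ± 1.92 to 10.9 ± 1.41 FPKM (log2 fold change −0.99, SE 0.10, adjusted p = 0.000224), and CYP51A1, a sterol demethylase gene, from 16.8 ± 0.592 to 12.1 ± 0.51. Oxidative phosphorylation and mitochondrially encoded genes had medians of 0.10 and 0.17, above 0 in 2 and 3 of 4 pairs, with camera adjusted p = 0.00946 for each, and adjusted p = 0.605 and 0.487 with an estimated correlation. In the first 1 of 25 was higher (NDUFA1, adjusted p = 0.0487, and 0.0601 with the pair block) and 1 lower (CYCS, with an adjusted p of 0.093 with median-of-ratios scaling), in the second 1 of 13 was higher (MT-CYB, adjusted p = 0.0324, and 0.0608 with the pair block), and 0 passed adjusted over the list alone in either. They did not pass with quantile normalisation (adjusted p = 0.405 and 0.918), and the first did not with the GC and length trend removed (adjusted p = 0.246).

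Vascular tone genes had 3 of 19 higher and 6 lower over all genes, and 6 and 7 adjusted over the list alone (camera adjusted p = 0.951). NOS3, the endothelial nitric oxide synthase gene, rose from 53 ± 4.01 to 77.1 ± 4.2 FPKM (log2 fold change 0.53, SE 0.07, adjusted p = 0.000924). Proliferation genes gave 0 of 31 calls over all genes or adjusted over the list alone in the unblocked fit, and 4 lower with the pair block, among them CENPE (−0.49, adjusted p = 0.0272) and KIF11 (−0.50, adjusted p = 0.0338), with a median of −0.26 that was −0.54 in P6 and 0.05 in P7 (camera adjusted p = 0.357). Of 5 lymphatic endothelium markers 1 was higher, STAB1 (camera adjusted p = 0.537). Marker genes of smooth muscle, fibroblasts, leukocytes and epithelium had 3, 3, 4 and 3 tested members. Among them the muscle gene TAGLN averaged 130 against 114 FPKM and the collagen gene COL1A2 45 against 44.4, the muscle gene SMTN rose from 47.9 ± 3.59 to 66.1 ± 8.25 (log2 fold change 0.45, SE 0.10, adjusted p = 0.0098), and the keratin gene KRT18 rose from 73.8 ± 2.49 to 115 ± 23.4.

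**Figure D4:**
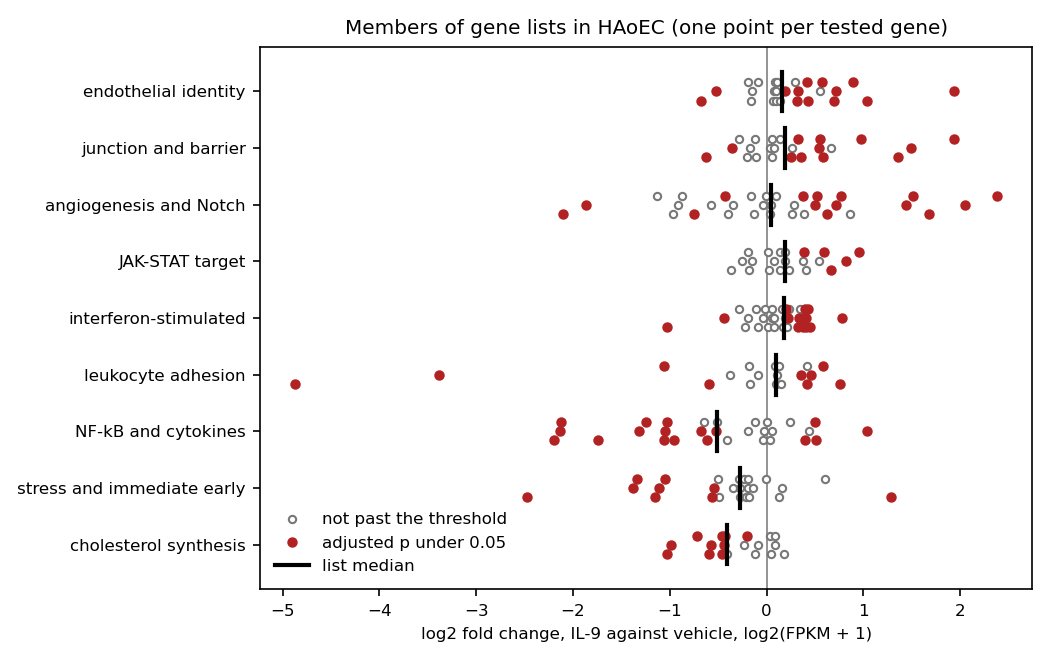
Log2 fold change of each tested member of the HAoEC gene lists, IL-9 against vehicle, as points, red for an adjusted p under 0.05, with a black mark at each list's median. Endothelial identity genes had 11 red points above 0 and cholesterol synthesis genes 10 below 0.

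Of 23 lists tested, 9 passed camera at the preset correlation, 7 upward and 2 downward, 0 passed with an estimated correlation, and 14 passed fry. With the GC and length trend removed, 6 of the 9 passed. With the pair block 8 STAT targets were higher and 0 lower, and 6 vascular tone genes were higher and 4 lower. The IL-9 effect differed between P6 and P7 for 249 of 12944 genes as an interaction term, among them DLL4 (difference −1.47, adjusted p = 0.00183) and SELE (1.75, adjusted p = 0.00388). In vehicle libraries the same 2 genes differed between P7 and P6 the other way, by 1.89 for DLL4 and −2.51 for SELE.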

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

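The tests of cells of other types in the IL-9+ sort and of a share of reads taken by abundant transcripts were chosen after the result was seen, as were the values without the undated sorts and the comparison of regulatory T cell genes with pan T cell markers.

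Markers of monocytes, neutrophils, B cells and basophils had medians above 0 in every sort batch, IL-9+ against IL-9−, although the sort gated on TCR-beta+ CD8− events and excluded doublets and dead cells, which would remove such cells. A share of the reads taken up by a few abundant transcripts is argued against as the cause of these increases. The share of FPKM held by the 10 most abundant genes would raise all other genes by at most 0.011 on the log2 scale in any pair. The lowest pair median of the monocyte and macrophage markers was 2.44 (SD over pairs 0.626). In pairs 4 and 5 the 10 most abundant genes held more of the IL-9+ library (28.96% against 16.81%, and 23.99% against 15.41%), which would lower other genes. RNA or cells of other types in the IL-9+ sort is a candidate explanation: the pan T cell markers lay lower in 4 of 5 pairs, with a mean pair median of −0.718 (SD 0.715), as fewer T cell transcripts would give, and abundant markers such as S100a9 (12000 against 1310 FPKM) and Lyz2 (852 against 58.1) were present. Of the 19 monocyte and macrophage markers in the table, 12 averaged at least 1 FPKM in IL-9− cells too, and in pair 3 the pan T cell markers were not lower (median 0.06) while the monocyte markers were higher (median 2.69). A change inside IL-9+ T cells themselves stays open, since no test here separates transcripts by cell.

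Of 19 regulatory T cell genes 7 were lower in IL-9+ libraries. Dilution of T cell RNA by other cells may account for part or all of it and cannot be told apart from a smaller share of regulatory cells among IL-9+ cells: the list's median lay below that of the pan T cell markers by a mean of −0.242 over 5 pairs (SD 0.206, below 0 in 4 of 5). A biological difference in the share of regulatory T cells stays open and was not tested.

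In HAoEC, 3068 genes passed although IL9R lay between 0.02 and 0.09 FPKM in all libraries. Pseudoautosomal copies were left out and were not added to any gene's value, that of IL9R included. GC content and transcript length, as taken from mouse genes, are argued against as the whole cause. Of the 2514 called genes with a value, 73.9% still passed with the same sign once the trend was removed. So did 21 of 21 genes named for their size, which were picked for large changes and so test it little. Of the called genes named from lists, some lost the call, among them CYCS (adjusted p = 0.683) and NDUFA1 (0.0977), and others kept it. Mouse values may remove the trend of human genes only in part. Direct signalling through the receptor stays open: of the feedback genes CISH, SOCS1, SOCS2, SOCS3 and PIM1, 2 were higher (SOCS1 and SOCS3), SOCS2 did not pass (adjusted p = 0.15, and 0.0267 with the pair block), nor did PIM1, and CISH was too low to test. The shared receptor chain gene IL2RG also lay low, between 0.04 and 0.42 FPKM, and JAK3 between 0.34 and 1.14. No depth is known, so low levels of IL9R and IL2RG may still give receptor protein, and nothing here measures protein.

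In T cells 2 of 100 splits drawn, the real one included, gave 755 genes or more. The other gave 837 and exchanged IL-9+ replicate 3 and IL-9− replicate 5, and the next highest gave 172. In HAoEC 1 of 35 splits, the real one, gave 3068, and the highest of the others gave 7. Counts as high as the real ones were rare over these splits. The splits treat the libraries as unpaired, although the codes were taken to pair them, so they do not exclude a random division within pairs. Splits that part all pairs, as the real one does, numbered 9 in T cells and 8 in HAoEC with the real one, too few for a share under 0.05, and the highest of the others gave 0 genes in each.

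A sample stood apart from the others of its group in 11 of 158 sets of values examined, where chance gives about 1 in 20; each value is the gap to the next sample divided by the group's range. IL-9− replicate 5 was highest for Il1b (0.837; 156.3 FPKM, next 30.94), Clec4e (0.809; 68.02, next 13.45), F10 (0.769), Cd36 (0.733) and Tyrobp (0.723). IL-9+ replicate 3 was highest for Tnfrsf9 (0.933; 331.1 FPKM, next 81.01), and 1 IL-9+ library was highest for Ikzf4 (0.719). The share of haemoglobin FPKM was highest in 1 IL-9− library (0.744; 0.44%, next 0.12%), and the median FPKM lowest in 1 IL-9+ library (0.729). Among vehicle HAoEC, 1 library had the most genes with an FPKM of 1 or more (0.895) and 1 had the highest NEAT1 (0.914; 333.2 FPKM, next 272.5).

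The IL-9 effect in HAoEC differed between P6 and P7 for 249 genes by an interaction term in limma, with 1733 at an unadjusted p under 0.05. Given as P7 minus P6 in log2 fold change, the difference was −1.47 for DLL4, −1.19 for EGR1, −1.09 for EFNA1 and −0.907 for N4BP3. It was 1.75 for SELE, 1.63 for ATOH8, 1.46 for CXCL8, 1.38 for PTGS2 and 1.00 for C14orf132. The adjusted p-values lay between 0.00183 and 0.0339. In vehicle libraries each of these 9 genes differed between P7 and P6 in the opposite direction: by 1.89 for DLL4, 1.21 for EGR1, 1.06 for EFNA1, 1.23 for N4BP3, −2.51 for SELE, −1.92 for ATOH8, −1.84 for CXCL8, −1.83 for PTGS2 and −1.03 for C14orf132. The interaction subtracts the difference in vehicle libraries from the one with IL-9, so an opposite direction in vehicle partly follows from how it is calculated. With IL-9, EFNA1 measured 135.22 and 145.18 FPKM in P6 and 143.91 and 130.45 in P7, and EGR1 2.55 and 2.67, and 2.74 and 2.6. With vehicle, EFNA1 measured 17.78 and 19.03, and 43.99 and 35.32, and EGR1 13.09 and 11.57, and 29.03 and 30.69. For these 2 genes the difference lay in the vehicle libraries. SELE also differed with IL-9 (1.52 and 2.51 in P6, 0.55 and 0.97 in P7). For the 9 genes as a set, a difference in the response to IL-9 was not told apart from one in the vehicle level.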

How the results depend on the processing

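The alternatives without the undated sorts, without pair 3, relative to pan T cell markers and with the GC and length trend removed were chosen after the data were seen, as were TPM and quantile normalisation for lists and named genes.

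Where not stated, the cause of a difference was not tested. T cell calls (755; 533 higher, 222 lower) were 3285 (1819 and 1466) with array weights, 2493 (1397 and 1096) with the pair as a replicate block, 3362 (1655 and 1707) with the sort batch as a covariate, 350 (310 and 40) with fewer samples once the undated sorts were left out, and 1319 (863 and 456) without pair 3. Lower genes numbered 454 with TPM, 124 with median-of-ratios scaling, 376 with quantile normalisation and 76 at an absolute log2 fold change of at least 1, a stricter criterion. Relative to pan T cell markers 868 genes were higher and 1 lower, as a reference that itself fell would give. On that scale, which raises all genes, Foxp3 (adjusted p = 0.197), Tigit (0.0812), Itgb8 (0.0846), Ikzf4 (0.415) and Tnfrsf18 (0.211) did not pass and Il9 did (0.026), so these calls cannot be read as tests of the genes. Without single libraries the counts ranged from 230 to 1624 (181 to 1082 higher, 47 to 542 lower): 1624 without IL-9+ replicate 3, 441, 303 and 266 without IL-9+ replicates 2, 4 and 5, 505 without IL-9+ replicate 1 (with 126 lower), and 230, 234, 486 and 271 without IL-9− replicates 1, 2, 3 and 4. Of the 24 T cell genes named for their size, all kept the call with the block, TPM, median-of-ratios scaling and quantile normalisation, 23 with a pseudocount of 0.1, 14 without the undated sorts, and between 16 (without IL-9+ replicate 5) and 24 without single libraries.

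HAoEC calls (3068; 1107 higher, 1961 lower) were 246 (91 and 155) at an absolute log2 fold change of at least 1, and lower genes numbered 1295 (with 1326 higher) with the GC and length trend removed, among 10195 genes with a value, of which 959 were higher and 1693 lower before. With the D and P codes as covariates 3960 genes passed (1541 higher and 2419 lower). The replicate block called 3119 (1180 and 1939) and held 2718 of the 3068. Without single libraries they ranged from 1944 to 2948 (720 to 1090 higher, 1219 to 1887 lower), with 1944 without IL-9 replicate 1 and 2028 without vehicle replicate 1. All 24 genes named for their size kept the call under the block, TPM, median-of-ratios scaling, quantile normalisation, a pseudocount of 0.1 and each library left out. Of the lists, 14 in T cells and 9 in HAoEC passed camera; 0 and 0 passed with an estimated correlation and 4 and 14 passed fry.

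Among the genes named under the rule, signs changed for some that did not pass, and of all 755 T cell calls 99.7% had the same sign in the second sort date. Without the undated sorts the log2 differences were −0.27 for Cd44, 0.16 for Trbc1 and 0.30 for Trbc2. STAT2 was 0.0204 with median-of-ratios scaling, 0.0280 with quantile normalisation and −0.0987 to 0.0692 without single libraries. STAT5A was −0.0491 with TPM and −0.0595 to 0.0612 without single libraries. STAT6 was −0.0469 with TPM, −0.00322 with quantile normalisation and −0.0545 to 0.0915 without single libraries. The replicate block gave calls to 41 more T cell genes under the naming rule, Il9 among them, and to 5 in HAoEC, and outside the rule to Igkc, Lyz2 and S100a9 in T cells and to SOCS2, ID2 and SMAD6 in HAoEC. Among the genes and lists given by name it ended the calls of NDUFA1, MT-CYB and the secreted cytokine list, added lists as reported and senescence genes in HAoEC (adjusted p = 0.0351, with 0.163 unblocked), and changed no other call of these. Depth is unknown, so changes of genes with low FPKM are the least certain.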

Other observations

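ICAM1, SMAD6, ID2, HEY1, HEY2 and DDIT4 were chosen after their values were seen.

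Among T cell lists not described so far, receptors of exhaustion and coinhibition went both ways in IL-9+ cells, with 2 of 14 higher and 1 lower over all genes, and 2 and 3 adjusted over the list alone (camera adjusted p = 0.413). Cd244a, an inhibitory receptor also found on NK and myeloid cells, rose from 1.31 ± 1.77 to 13.8 ± 5.31 FPKM (log2 fold change 2.85, SE 0.42, limma adjusted p = 0.00611, higher in 5 of 5 pairs), and Entpd1, an ectonucleotidase, from 8.74 ± 2.67 to 31.9 ± 18.7. Of 24 chemokine receptor and homing genes 1 was higher, Ccr1, and 1 lower, Cxcr6, over all genes and adjusted over the list alone (camera adjusted p = 0.764). Ccr1, which monocytes and granulocytes carry, rose from 3.64 ± 3.39 to 48.9 ± 23.4 FPKM, beside monocyte markers with a median of 3.14. Of 24 activation genes 1 was lower, Tnfrsf9, in both counts (camera adjusted p = 0.369), and with the pair block 9 were lower and 2 higher.

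In HAoEC, genes of matrix and endothelial-mesenchymal transition gave 7 of 32 lower and 0 higher, over all genes and adjusted over the list alone, with a median of 0.03, a mean of −0.21 and a downward test direction (camera adjusted p = 0.691). CCN1, a matrix protein gene induced by mechanical signals, fell from 320 ± 15 to 171 ± 17.5 FPKM (log2 fold change −0.91, SE 0.08, limma adjusted p = 0.000142, lower in 4 of 4 pairs), and CCN2 from 1282 ± 230 to 788 ± 57.9. Of 21 oxidative stress genes 2 were higher and 5 lower over all genes, and 4 and 5 adjusted over the list alone (camera adjusted p = 0.907). The cystine transporter gene SLC7A11 fell from 36.1 ± 5.33 to 10.4 ± 2.62 and NOX4, an oxidase gene, from 15.1 ± 1.76 to 7.08 ± 0.953. Tissue factor, F3, fell from 2.06 ± 0.429 to 0.472 ± 0.0574 in a coagulation list of 24 with 2 higher and 1 lower over all genes, and 0 and 1 adjusted over the list alone. That list's median was 0.05 and its mean −0.06 (camera adjusted p = 0.805). Of 28 glycolysis and hypoxia genes 3 were higher and 5 lower in both counts (camera adjusted p = 0.315), with NDRG1, a hypoxia-responsive gene, at −1.08. ICAM1, another adhesion molecule of inflamed endothelium, measured 30.6 ± 8.59 FPKM with IL-9 and 45.7 ± 4.9 with vehicle (log2 fold change −0.60, SE 0.17, limma adjusted p = 0.0307).

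Among the genes whose IL-9 effect differed between P6 and P7, SMAD6, an inhibitor of BMP signalling, had a log2 difference of −4.05 in P6 and −0.80 in P7 (interaction 3.25, SE 0.11, limma adjusted p = 6.53e-05). ID2, a BMP target, had −3.77 and −0.68, the Notch and BMP targets HEY1 and HEY2 had −2.10 and −2.04 in P6 and 0.27 and 0.30 in P7, and DDIT4 had 2.61 and 0.40. In vehicle libraries the log2 difference, P7 minus P6, was −3.47 for SMAD6, −3.36 for ID2, −2.03 for HEY1, −2.435 for HEY2 and 2.01 for DDIT4. For these genes too, a difference in the response to IL-9 was not told apart from one in the vehicle level. Between P7 and P6, 1490 genes differed in vehicle libraries.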
